A study of Macaca fascicularis with 4 samples.

How the data were processed

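The data are 4 two-colour Agilent rhesus macaque arrays for comparative genomic hybridisation, all on 1 slide, with 180880 spots each, of which 173895 are genomic and 6985 are controls. Per the labels, the experimental DNA was labelled with Cy5 and the female adipose DNA with Cy3 on every array, including the array of adipose against adipose, and no dyes were swapped. The labels describe the stem cells as monkey parthenogenetic haploid embryonic stem cells grown on feeder cells. Groups follow the labels of the Cy5 channel: MPH1-P11, MPH2-P5, MPH1-P20 and the adipose self-hybridisation, with 1 array each. With 1 slide there was no slide batch to test. The array was designed on the rhesus genome while the DNA came from cynomolgus monkeys, so sequence differences under a probe can change its signal on either channel. Probe positions are those of the files (rheMac2), and nothing was converted to another build.

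Per the file headers, the authors' scanner images were processed with Agilent Feature Extraction 10.7.3.1, and the submitters' processing notes name version 10.7. The deposited intensity values of both channels are background-subtracted with spatial detrending, corrected for a multiplicative trend, and scaled with a linear dye factor, per the file headers. The deposited median intensity of each spot and of its local background is not corrected. The deposited LogRatio is the log10 of Cy5 over Cy3. The authors' series table holds log10 ratios that equal this column in every row, with column medians of -0.000667, 0.000902, 0 and 0 in MPH1-P11, MPH2-P5, MPH1-P20 and the self-hybridisation. Its scale and direction are therefore known, and it is not centred further. Flags for outlier, saturated and dim spots were also taken from the deposited files as given by Feature Extraction.

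From these values the log2 ratio of the processed Cy5 and Cy3 signals was computed for each spot. Control spots and spots flagged as non-uniform or population outliers were dropped, repeated spots of a probe were averaged, and each array was centred on its median. Without loess or quantile normalisation, broad trends remain in the ratios. Of 171495 probes with a position, 192 were left out because of flags. A probe was called not well above background when Feature Extraction flagged it so. Means of some regions with such probes are also given as bounds, and those of others only as they are. For a bound, each dim probe was put at the higher of its own signal and the lowest signal of probes well above background. The signal over background of the Cy5 channel was 11.1 in MPH1-P11, 10.4 in MPH2-P5, 11.6 in MPH1-P20 and 11.7 in the self-hybridisation. The number of arrays limits the precision of each comparison.

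Segments were found by penalised least squares with exact optimal partitioning, along each chromosome, with a penalty per change point of 3 times the noise variance times the natural log of the number of probes. Single probes beyond 4 noise SD of their neighbours were shrunk first. A call needed at least 5 probes and an absolute mean log2 ratio of 0.3. The same rule was applied to the probe-wise differences MPH1-P20 minus MPH1-P11 and MPH1 (mean of both arrays) minus MPH2-P5. Calls were counted as shared when they had the same direction and overlapped by 50% of the probes of the shorter, with 1000 circular shifts as the chance level. The background of each call was 10000 windows from the self-hybridisation. Intervals for X minus autosomes are 95% bootstrap intervals of 1000 draws over blocks of 50 probes. The alternatives were run on the 10 calls with the largest absolute mean times the square root of the number of probes in each profile, a rule set before the data were examined, as were the settings above and the alternatives. The text names only some of these 50 calls, picked after their values were seen. The regions named outside this rule, also chosen then, are those on chromosomes 1, 5 (181952172 to 182074960) and 14 in MPH1-P20 minus MPH1-P11, and those on chromosomes 3, 4 (32255283 to 32389251) and 17 (84371245 to 84502697) in MPH1-P20. The shuffled probe order, the simulated losses, the counts of long shallow calls and the counts of far-off probes were also chosen after the data were seen.

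The segmentation was tested on simulated data: Gaussian noise of each array's size over its 171303 probes, with segments of known size added. Outside the added segments, 0 calls were made. Simulated changes of known size were added to the real arrays at 100 places each. A loss of 0.58 over 20 probes was found in 98% of trials in MPH1-P11, 50% in MPH2-P5 and 82% in MPH1-P20. Over 50 probes it was found in 100% on all 3. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0 was used, and R 4.3.3 with limma 3.58.1 for the normexp background correction with an offset of 50.

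The alternatives were penalties of 2 and 6, a hidden Markov model, size thresholds of 0.2 and 0.5, minimums of 3 and 10 probes, no shrinking of outliers, normexp on spot medians, the authors' log10 ratios, subtraction of the self-hybridisation, the 170625 probes well above background on all arrays, removal of a running median over 500 probes, centring on autosomes or on the mode, and other overlaps for shared calls. A correction for GC content needs a genome sequence of the array's build, which was not used here, and the running median took its place. The planned gene list log2 ratios were not run, and no region is tied to a gene, because the files' gene annotation column held no names and the gene table at hand is of another assembly. Genes and exons of the regions are not analysed here. No test between groups was run, since each group is 1 array.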

Results

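Genomic DNA of parthenogenetic haploid embryonic stem cells of the cynomolgus monkey (Macaca fascicularis) was compared with genomic DNA of female monkey adipose cells by array comparative genomic hybridisation. Parthenogenetic haploid embryonic stem cells derive from an egg without a sperm genome and carry a single chromosome set. The 4 arrays held DNA of line MPH1 labelled P11, of line MPH1 labelled P20, of line MPH2 labelled P5, and of the adipose cells themselves hybridised against adipose DNA. The P numbers are not spelled out in the labels; they are used here as names only. Stem cell DNA was labelled with Cy5 and adipose DNA with Cy3, so a positive log2 ratio means more DNA in the stem cells than in adipose cells, relative to the median probe. The arrays give copy number relative to that median and do not show whether the cells were haploid. Each sample was hybridised once, so no value below has a replicate check and no p-value is given. Standard errors (SE) are over the probes of a region and cover probe spread only.

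After flagged spots were left out, 171303 probes on 20 autosomes and the X chromosome were used, with a median spacing of 14940 bp. The median Cy5 signal was 630 on the MPH1-P11 array, 580 on MPH2-P5, 652 on MPH1-P20 and 644.5 on the self-hybridisation, over local backgrounds of 55 to 57. The noise between neighbouring probes (the SD of their differences divided by the square root of 2) was 0.233 in MPH1-P11, 0.329 in MPH2-P5, 0.256 in MPH1-P20 and 0.128 in the self-hybridisation. The scanner software's own quality metric placed MPH2-P5 outside its range. A simulated loss of 1 log2 unit over 5 probes, added to the real arrays, was found in 82% of 100 trials in MPH1-P11, 61% in MPH1-P20 and 12% in MPH2-P5. Over 10 probes the same loss was found in 100%, 100% and 90% of trials.

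The first question was whether the stem cells kept all chromosomes. No chromosome was gained or lost as a whole on any of the 4 arrays, at a threshold of 0.3 for the absolute chromosome median. Autosome medians ran from -0.041 on chromosome 5 to 0.032 on chromosome 10 in MPH1-P11. They ran from -0.072 on chromosome 5 to 0.150 on chromosome 19 in MPH2-P5, and from -0.100 to 0.161 on the same chromosomes in MPH1-P20. In the self-hybridisation the range was -0.011 to 0.026, again from chromosome 5 to chromosome 19. By calculation, a whole extra chromosome would reach the threshold if it was present in 23.1% or more of haploid cells. A missing one would if it was absent from 18.8% or more. For cells with a doubled chromosome set these limits are 46.2% and 37.5%. The limits assume a chromosome otherwise at 0 and ratios that follow copy number in full. For chromosomes off 0, such as 19 at 0.161 and 5 at -0.100 in MPH1-P20, they differ. No change of a whole chromosome was simulated.

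**Figure D1:**
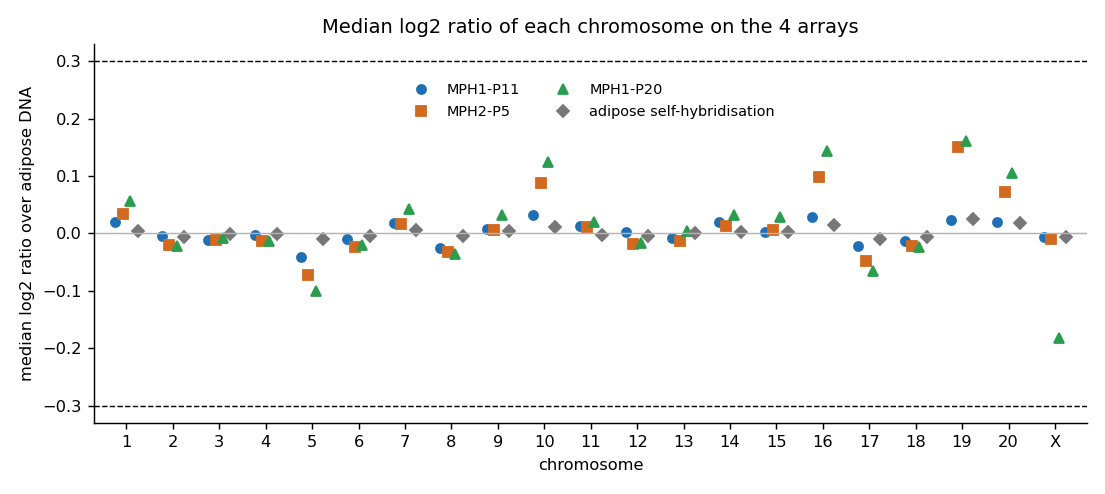
Median log2 ratio over adipose DNA (vertical axis) of each chromosome (horizontal axis) on the 4 arrays, 1 point per array; dashed lines mark the threshold of 0.3 in either direction. No point reaches a dashed line, and the X chromosome of MPH1-P20 lies lowest, at -0.182.

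The X chromosome of the array labelled MPH1-P20 lay below its autosomes. X minus autosomes was -0.193 there (95% bootstrap interval over blocks of 50 probes -0.211 to -0.174), which puts X at 87.5% of the autosome level. In MPH1-P11 the difference was -0.007 (-0.017 to 0.003), in MPH2-P5 -0.011 (-0.027 to 0.007) and in the self-hybridisation -0.007 (-0.010 to -0.003). A stem cell with 1 X per chromosome set would give 0 against a female control, whether haploid or diploid. In the probe-wise difference MPH1-P20 minus MPH1-P11, X minus autosomes was -0.183 (-0.195 to -0.170). The intervals cover probe spread within an array and not the spread between hybridisations.

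Regional gains and losses were called in each stem cell sample, and the self-hybridisation had 0 calls. MPH1-P11 held 11 called segments, of which 6 were gains and 5 losses. MPH2-P5 held 11, with 3 gains and 8 losses, and MPH1-P20 held 29, with 9 gains and 20 losses. Excluding probe-free gaps over 500 kb, the called segments covered 2.67 Mb in MPH1-P11, 1.92 Mb in MPH2-P5 and 44.4 Mb in MPH1-P20. None of 10000 windows of equal probe number drawn from the self-hybridisation was as large as any of these calls, although that array was the least noisy of the 4. With the probes in shuffled order, 20 times per array, no call was made on any array. The counts depended on the calling method: a hidden Markov model called 6, 5 and 55 segments in MPH1-P11, MPH2-P5 and MPH1-P20. The split of gains and losses moved too: in MPH2-P5 to 1 and 8 after another background correction (normexp) and to 4 and 5 over probes well above background, and in MPH1-P11 to 5 and 7 after subtraction of the self-hybridisation and to 4 and 5 after removal of a running median.

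Some regions were low or high in all 3 stem cell samples. The arrays cannot assign these to the stem cells or to the adipose DNA that all of them share. On chromosome 20, 9 probes between 33533879 and 44468094 (rheMac2) averaged -2.24 ± 0.36 (SE) in MPH1-P11, -2.40 ± 0.35 in MPH2-P5 and -1.77 ± 0.61 in MPH1-P20, against -0.02 ± 0.06 in the self-hybridisation. These probes lie in 2 groups on either side of a stretch of 10817.1 kb without probes, from 33607634 to 44424701, so the call says nothing about that stretch. Of the 9 probes, 6, 6 and 5 were not well above background in the stem cell channel. On the processed signals, with those probes set at the detection limit, the stem cell DNA was at least 2.33-fold lower in MPH1-P11, at least 2.47-fold in MPH2-P5 and at least 2.08-fold in MPH1-P20. These bounds hold only for the mean of all 9 probes on the processed signals. With normexp, whose offset of 50 pulls dim probes toward 0, the means were -0.64, -0.95 and -0.63. Over the region's probes well above background on all arrays they were -1.24, -1.35 and -0.87 in the same order. The value of MPH1-P20 is a smaller loss than its bound, which is -1.06 in log2. On chromosome 5, 10 probes from 60494221 to 60569237 averaged -0.97 ± 0.17 in MPH1-P11, -0.89 ± 0.08 in MPH2-P5 and -1.08 ± 0.12 in MPH1-P20. On chromosome 13, 8 probes from 89746861 to 89790884 averaged 0.89 ± 0.08, 0.77 ± 0.15 and 0.96 ± 0.26 in the same order, and -0.24 ± 0.18 in the self-hybridisation.

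Of the 11 calls of MPH2-P5, 5 overlapped a call of the same direction in MPH1, counting both MPH1 arrays. The mean after 1000 random shifts of the calls along the genome was 0.097 and the highest count 2. Of the 5, only 3 were called in both MPH1 arrays. The loss on chromosome 17 was shared with MPH1-P20 only, and MPH1-P11 averaged 0.54 there. The loss on chromosome 9 was shared with MPH1-P11 only, and MPH1-P20 averaged 0.45 there. All arrays used 1 control DNA, so this overlap includes any copy number change of the adipose DNA itself. The shared count of 5 fell to 2 after the normexp background correction and to 1 with the hidden Markov model.

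The next comparison asked where MPH1 and MPH2 differ, using the mean of both MPH1 arrays minus MPH2-P5, in which the control DNA cancels. MPH2 was sampled only at P5 and MPH1 only at P11 and P20, so line and P number cannot be told apart here. It held 10 called regions, 7 higher in MPH1 and 3 higher in MPH2. The split was 4 and 3 over probes well above background and 8 and 2 with normexp. It stayed at 7 and 3 after removal of a running median and with centring on autosomes or the mode. The most probes behind any MPH2 loss of over 1 log2 unit lay on chromosome 6, where all 20 probes from 28656959 to 28998596 were below 0 in MPH2-P5. Their mean was -1.86 ± 0.20, which is 27.5% of the control level, against -0.10 ± 0.10 in MPH1-P11 and -0.30 ± 0.06 in MPH1-P20. On chromosome 10, 10 probes between 59094559 and 60776870 averaged -1.32 ± 0.17 in MPH2-P5, 0.16 ± 0.12 in MPH1-P11 and -0.05 ± 0.10 in MPH1-P20. That segment includes 1529.96 kb without probes, from 59246854 to 60776811. Its last probe, which ends at 60776870, lies alone beyond that stretch, so the call says nothing about the stretch. On chromosome 13, 5 probes from 113278302 to 113304516 averaged -2.995 ± 0.78 in MPH2-P5. There 3 of the 5 were not well above background, which makes the loss at least 4.13-fold on the processed signals; with normexp the mean was -1.39, a smaller loss than that bound. In the same region MPH1-P11 was at -0.73 ± 0.89 and MPH1-P20 at 0.31 ± 0.33. Also on chromosome 13, 8 probes from 89461924 to 89516278 averaged -2.68 ± 0.64 in MPH2-P5, 0.46 ± 0.09 in MPH1-P11 and -0.25 ± 0.59 in MPH1-P20. There 5 of the 8 were not well above background in MPH2-P5, a loss of at least 4.20-fold on the processed signals. MPH1 minus MPH2 was 2.79 in this region and 1.24 over its probes well above background on all arrays.

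On chromosome 8 the lines lay on opposite sides of the control. Over 26 probes from 8068021 to 8237440 the mean was 0.70 ± 0.11 in MPH2-P5, -0.55 ± 0.12 in MPH1-P11 and -0.46 ± 0.09 in MPH1-P20. Over 7 probes from 7085255 to 7139547 it was 1.15 ± 0.14, -0.58 ± 0.30 and -0.95 ± 0.37. On chromosome 4, 7 probes from 32181360 to 32275374 averaged 0.35 ± 0.30 in MPH2-P5, -2.24 ± 0.49 in MPH1-P11 and -1.19 ± 0.75 in MPH1-P20, with 4 of the 7 not well above background in MPH1-P11. MPH1 minus MPH2 was -2.07 there and -0.79 over probes well above background. On chromosome 9, from 39109304 to 39613248, the call rests on MPH1-P20 alone, since the mean was 1.18 ± 0.43 there, -0.47 ± 0.25 in MPH1-P11 and -0.57 ± 0.32 in MPH2-P5. On chromosome 17, from 8056 to 493589, it rests on MPH1-P11 alone. With only MPH1-P11 as the MPH1 sample 9 regions were called, and with only MPH1-P20 14, a check added after the data were seen. The hidden Markov model called 4 regions.

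The last comparison asked what differed within MPH1 between P11 and P20. The difference profile MPH1-P20 minus MPH1-P11 held 17 called regions, 10 higher in the P20 sample and 7 lower, against at most 1 in 20 shuffles of its probes. The count was 7 with the hidden Markov model, 8 with a minimum of 10 probes, 10 with a penalty of 6 and 32 with a penalty of 2. The split was 7 higher and 7 lower over probes well above background, and 7 and 6 with normexp. On chromosome 17, 13 probes from 8056 to 352311 averaged 0.54 ± 0.06 in MPH1-P11 and -0.83 ± 0.08 in MPH1-P20. All 13 were lower in the P20 sample, and MPH2-P5 was at -0.82 ± 0.10. On chromosome 7, 9 probes from 71138305 to 71283708 averaged 0.36 ± 0.07 in MPH1-P11, -0.75 ± 0.07 in MPH1-P20 and 0.02 ± 0.07 in MPH2-P5. On chromosome 14, 9 probes from 53730631 to 53768427 averaged 0.96 ± 0.06 in MPH1-P11 and 0.09 ± 0.11 in MPH1-P20. On chromosome 1, 19 probes from 122917886 to 123186613 averaged 0.06 ± 0.05 in MPH1-P11 and 0.65 ± 0.08 in MPH1-P20. On chromosome 5, 6 probes from 181952172 to 182074960 averaged 0.03 ± 0.07 and 1.09 ± 0.27.

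In some regions the P20 sample held DNA that was low in the P11 sample. On chromosome 13, 5 probes from 89722440 to 89746920 averaged -2.61 ± 1.16 in MPH1-P11 and 1.03 ± 0.19 in MPH1-P20. There 4 of the 5 were not well above background in MPH1-P11, which makes its loss at least 2.91-fold on the processed signals. MPH1-P20 minus MPH1-P11 was 3.64 there and 1.59 after the normexp background correction. Also on chromosome 13, 5 probes from 85570758 to 85635486 averaged -1.05 ± 0.19 in MPH1-P11 and 0.24 ± 0.14 in MPH1-P20. On chromosome 9, 24 probes from 38839436 to 39613248 averaged -0.45 ± 0.21 and 1.03 ± 0.36, a difference of 1.47 that was 0.78 over probes well above background. Because of such regions, the samples are called by their labels here, and no change over culture is read from them.

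**Figure D2:**
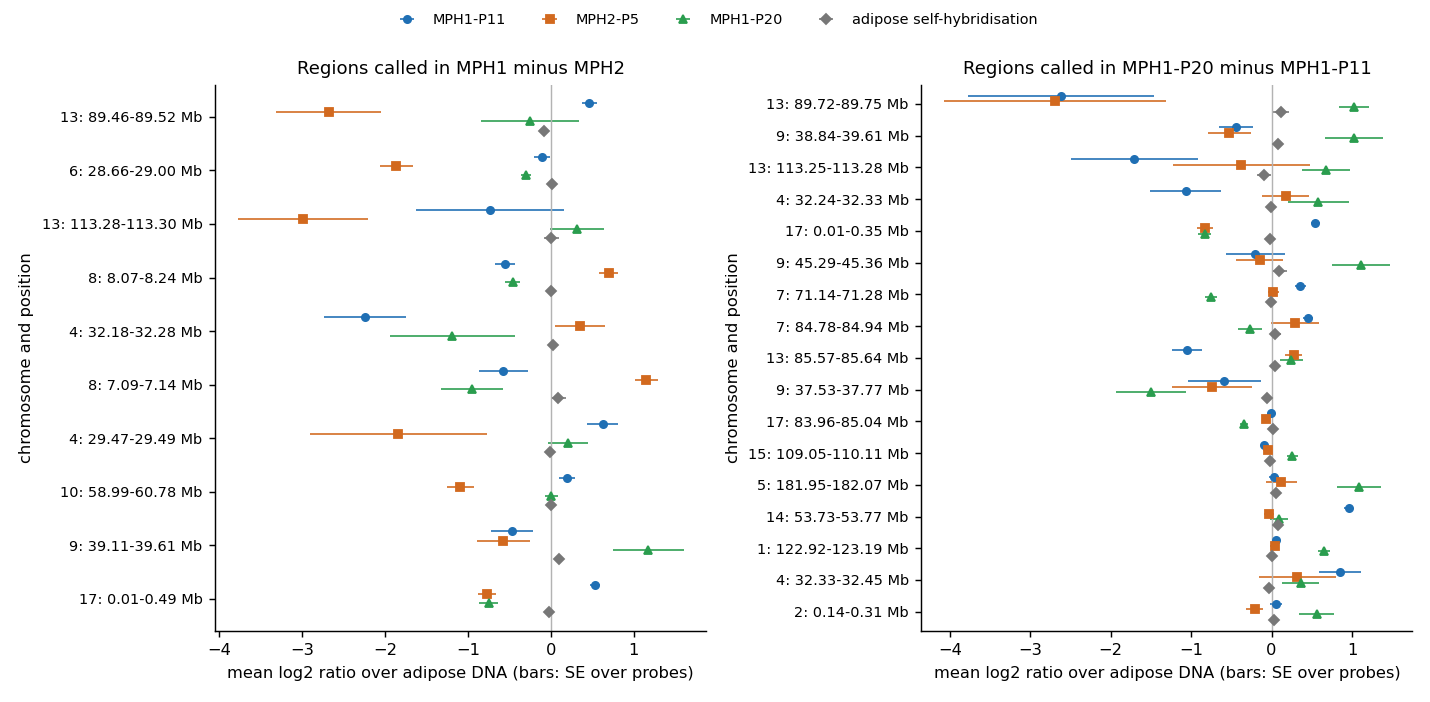
Mean log2 ratio over adipose DNA (horizontal axis) of each region (vertical axis, chromosome and position in Mb) called in MPH1 minus MPH2 (left) and in MPH1-P20 minus MPH1-P11 (right), 1 point per array with bars of 1 SE over probes. The self-hybridisation points lie near 0, and on chromosome 17 MPH1-P11 lies at 0.54 while MPH2-P5 and MPH1-P20 lie at -0.82 and -0.83.

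Of the 11 calls of MPH1-P11, 5 overlapped a call of the same direction in MPH1-P20. The mean after random shifts was 0.079 and the highest count 2. Of the same 11 calls, 4 overlapped a call of the same direction in MPH2-P5, with a mean of 0.005 after shifts and a highest count of 1. Random shifts do not account for the copy number of the shared control DNA. Over the probes of those 11 calls, MPH1-P20 lay past 0.3 on the same side in 4, on the opposite side in 1 and under 0.3 in 6. MPH2-P5 lay on the same side in 5, on the opposite side in 3 and under 0.3 in 3. Probe log2 ratios correlated between MPH1-P11 and MPH1-P20 at a Pearson r of 0.385, between MPH2-P5 and MPH1-P20 at 0.386 and between MPH1-P11 and MPH2-P5 at 0.308, across probes, which are not independent replicates. The correlations with the self-hybridisation were 0.282 for MPH1-P11, 0.120 for MPH2-P5 and 0.25 for MPH1-P20. The shared control DNA can raise the correlations between stem cell arrays. In the self-hybridisation adipose DNA is in both channels, so its copy number cancels there. Probe and dye bias common to the slide can raise all of these correlations. Neither share was measured. The hidden Markov model found 1 shared call of MPH1-P11 and MPH1-P20, and the normexp background correction 3.

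**Figure D3:**
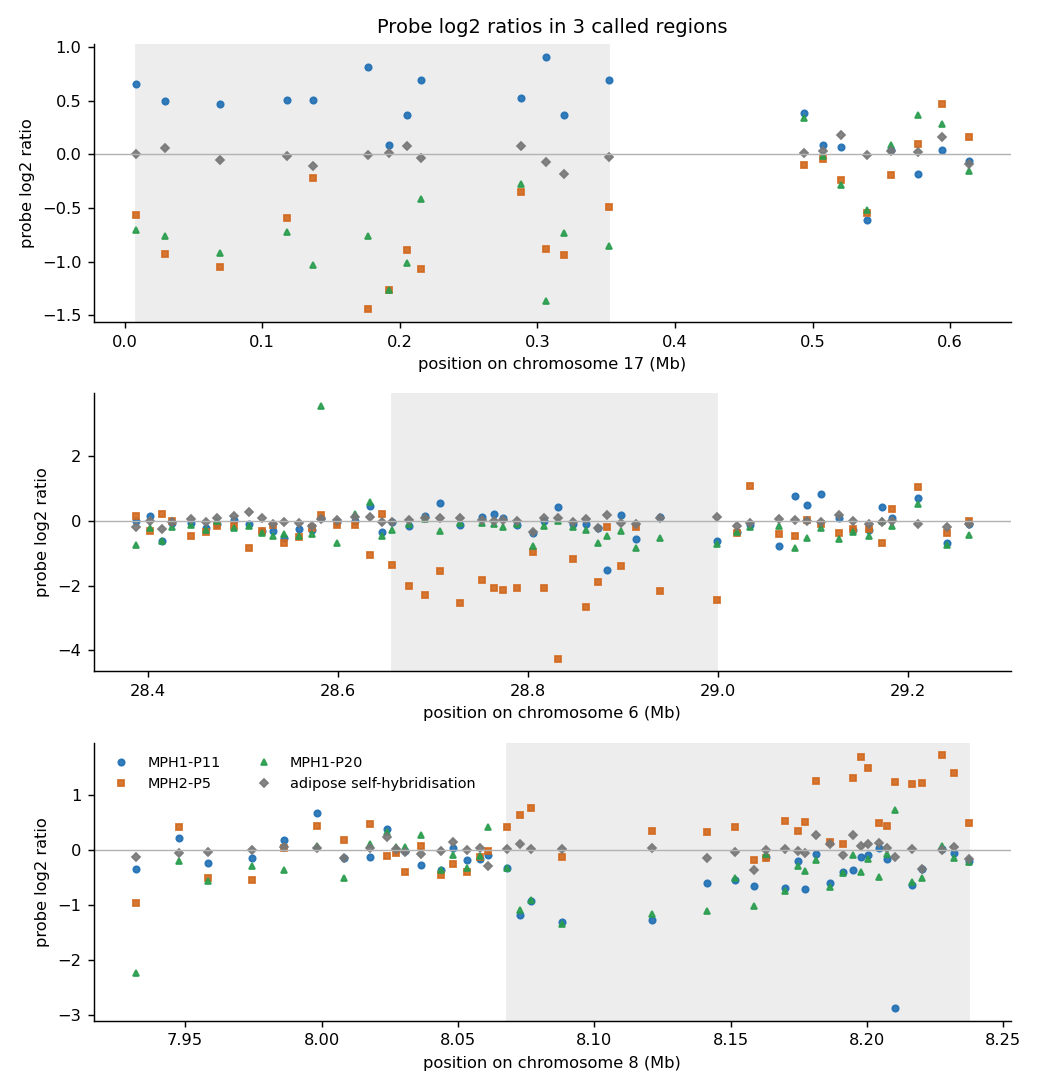
Probe log2 ratio over adipose DNA (vertical axis) against position in Mb (horizontal axis) on chromosomes 17, 6 and 8, 1 point per probe and array, with the called region shaded. The shaded probes average 0.54 in MPH1-P11 and -0.83 in MPH1-P20 on chromosome 17, -1.86 in MPH2-P5 on chromosome 6, and 0.70 in MPH2-P5 against -0.55 in MPH1-P11 on chromosome 8.

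The larger number of calls in MPH1-P20 came in part from long segments of small size. In all, 11 of its 29 calls were longer than 500 kb with an absolute mean under 0.4, 10 of them losses, and they covered 41.3 Mb. The longest was on X from 76762672 to 94775929, where 961 probes averaged -0.32 ± 0.01. Another on X, from 139970228 to 146322883, averaged -0.35 ± 0.02, and on chromosome 5 the 182 probes from 107577577 to 110670794 averaged -0.31 ± 0.02. After a running median over 500 probes was removed, 2 of these 11 calls remained. That filter removes by construction segments about as long as its window, such as those on X, so their loss is no test of them. The segment on chromosome 5 averaged -0.161 after it. With the self-hybridisation subtracted, that segment averaged -0.274, under the threshold of 0.3, and the longest on X averaged -0.303. Several of these means lie close to the threshold, so centring matters. MPH1-P20 had 24 calls with 15 losses when centred on the mode, and 32 with 23 losses when centred on autosomes. Among the short calls, MPH1-P20 alone was past 0.3 on chromosome 3 from 49728709 to 49824569, at 1.33 ± 0.12 over 5 probes. It alone was low by more than 0.3 on chromosome 17 from 84371245 to 84502697, at -0.96 ± 0.16 over 9 probes.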

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

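Of the tests below, those on noise, on DNA of another line, on deletion in culture, on a trend common to the slide and on the genome-wide trend at X were chosen after the result was seen; the tests on short probes and on the 4 equal parts of X were set out before. A first test on DNA of another line counted probes of MPH1-P11 low by over 1 that were low by over 0.5 elsewhere. Low here is against a running median over 51 neighbouring probes. In MPH1-P20 42.8% were so and in MPH2-P5 49.1%, which was read as fitting that explanation. This first test is void because 4.19% and 8.29% of all probes pass that cutoff. The test below, with the rule for its label, was written after its own values were seen. Each region below lay past 0.3 on opposite sides of the control in the samples compared; these differences were not tested, as each sample was hybridised once.

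Between the lines, whose samples also differ in P number, 3 regions stood on opposite sides. MPH1 minus MPH2 was -1.20 on chromosome 8 from 8068021 to 8237440, -1.92 on chromosome 8 from 7085255 to 7139547, and -2.07 on chromosome 4 from 32181360 to 32275374. In the last region 4 of 7 probes were not well above background in MPH1-P11, MPH2-P5 was at 0.35 ± 0.30 (SE), and the difference was -0.79 over probes well above background and -1.12 with normexp.

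Between the samples labelled MPH1-P11 and MPH1-P20, 6 regions did. MPH1-P20 minus MPH1-P11 was 3.64 on chromosome 13 from 89722440 to 89746920, 2.38 on chromosome 13 from 113248970 to 113278361, and 1.65 on chromosome 4 from 32244422 to 32328228. In MPH1-P11, 4 of 5 probes of the first region, 2 of 6 of the second and 3 of 12 of the third were not well above background. With normexp the differences were 1.59, 1.14 and 0.89, and over probes well above background the last 2 of these were 1.02 and 0.94, while the first region had under 3 such probes and no value was taken. MPH1-P20 minus MPH1-P11 was 1.47 on chromosome 9 from 38839436 to 39613248 (0.78 over probes well above background), -1.38 on chromosome 17 from 8056 to 352311 and -1.11 on chromosome 7 from 71138305 to 71283708.

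The samples of MPH1 differed at many probes and regions. Noise independent between probes is argued against for the called regions, because the difference profile held 17 calls in genome order and at most 1 in shuffled order. For single probes, noise between labellings was measured only in adipose DNA, on 1 array. There 10 probes lay below -1 and 15 above 1, against 1760 and 1104 in MPH1-P11 and 1229 and 1386 in MPH1-P20. Noise between labellings of stem cell DNA was not measured and stays open. Deletion in culture as the whole cause is argued against, because 10 of the 17 called regions were higher in MPH1-P20. Over probes well above background 7 of 14 were higher, with normexp 7 of 13 and after the running median 9 of 17. Centred on autosomes 10 of 18 were higher, and centred on the mode 11 of 18. Gains in culture were not tested. A sample whose DNA is not of the labelled line stays open, as the values point both ways. Low and high here are deviations from a running median over 51 neighbouring probes. Of 1750 probes low by over 1 in MPH1-P11, 44.1% (95% Wilson interval 41.7 to 46.4) were among the lowest 5% of MPH1-P20. Among those of MPH2-P5 were 44.9% (42.6 to 47.3). Of 1100 high ones 50.9% and 62.0% were among the highest 5%, in the same order. Of probes low or high by over 1 in MPH1-P20, 58.4% and 42.8% were so placed in MPH1-P11, and 52.0% and 39.4% in MPH2-P5. The intervals treat probes as independent and cover neither links between neighbouring probes nor the spread between hybridisations. Spearman's rho of log2 ratios over all probes was 0.396 between MPH1-P11 and MPH1-P20, 0.399 between MPH2-P5 and MPH1-P20 and 0.237 between MPH1-P11 and MPH2-P5. With the self-hybridisation rho was 0.382 for MPH1-P11, 0.129 for MPH2-P5 and 0.274 for MPH1-P20. An array without stem cell DNA thus came near the 0.396 of MPH1-P11 with MPH1-P20, so these correlations do not decide the line. A mixture of DNA was not tested.

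The second pattern is the 8 long shallow calls on autosomes of MPH1-P20, which cover 13.2 Mb; 3 others, of 28.1 Mb, lie on X and belong to the third pattern. A trend of equal size on all arrays of the slide is argued against, because the slope of the self-hybridisation on MPH1-P20 over 1613 autosomal windows of 100 probes was 0.103 (0.097 to 0.109 over resampled chromosomes). A trend with base composition stays open: autosomal window medians of MPH1-P20 rose with the share of probes shorter than 60 bases, which are commonly those rich in G and C, at a Spearman rho of 0.651 (0.581 to 0.707). The rho was 0.616 in MPH2-P5, 0.463 in MPH1-P11 and 0.495 in the self-hybridisation. Labelling bias and extra copies of early replicating regions in dividing cells would both give such a trend, and the test does not separate them.

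The third pattern is the low X chromosome of MPH1-P20. The genome-wide trend is argued against as the whole cause, because X windows lay -0.185 (-0.196 to -0.168) from the line that relates MPH1-P20 to MPH2-P5 on autosomes. Loss of only part of X is argued against, because the median distances from that line in 4 equal parts of X ran from -0.191 to -0.173. The log2 ratios themselves were uneven along X, where the called segments averaged -0.32, -0.35 and -0.39. Differences within a part were not tested. A lower dose of the whole X in some of the DNA stays open and was not tested; the value would be reached if 25.1% of the DNA came from cells with 1 X per 2 autosome sets, or if 12.5% of haploid cells lacked X.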

How the results depend on the processing

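The splitting of calls at probe-free gaps and the MPH1 minus MPH2 profiles with 1 MPH1 array were chosen after the data were seen; all other alternatives were listed before. Counts of calls moved by more than 1.5 times under these settings, and the cause was not tested where no construction explains it. A penalty of 2 gave 19 calls in MPH1-P11 and 32 in MPH1-P20 minus MPH1-P11. A penalty of 6 gave 6 calls in MPH1-P11, 5 in MPH2-P5, 12 in MPH1-P20, 10 in MPH1-P20 minus MPH1-P11, and 2 shared calls of MPH2-P5 with MPH1. The hidden Markov model gave 6, 5 and 55 calls on the same arrays, 7 in MPH1-P20 minus MPH1-P11, 4 in MPH1 minus MPH2, and 1 shared call in each overlap. A size threshold of 0.2 gave 21 calls in MPH2-P5, 92 in MPH1-P20, 28 in MPH1-P20 minus MPH1-P11 and 13 shared calls of MPH2-P5, and a threshold of 0.5 gave 17 in MPH1-P20. A minimum of 3 probes gave 31 calls in MPH1-P11, 24 in MPH2-P5, 17 in MPH1 minus MPH2, and 10 and 9 shared calls of MPH1-P11 and MPH2-P5. A minimum of 10 probes gave 7, 7, 8 and 5 calls in MPH1-P11, MPH2-P5, MPH1-P20 minus MPH1-P11 and MPH1 minus MPH2, and 2 and 3 shared calls. Normexp gave 3 and 2 shared calls, and probes well above background 3 shared calls of MPH1-P11.

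The self-hybridisation had 0 calls, and no chromosome was called, under every alternative run for them. X minus autosomes of each array moved by less than its interval. Of 50 regions, the first 10 calls of each profile, not all named in the text, none changed sign under the signal, filter and centring alternatives that gave it a value, which the restriction to probes well above background did for 47 and subtraction of the self-hybridisation for 30; normexp moved the mean of 7 beyond its interval, the running median that of 6, the restriction to probes well above background that of 4, and subtraction of the self-hybridisation and centring on the mode that of 1 each. The running median removes chromosome and X medians, and segments about as long as its window, by construction, so chromosome and X medians were not recomputed. The gene list alternatives were not run. No paired analysis was possible because each group is 1 array. Differences between neighbouring probes were largest on the MPH2-P5 array, so short changes may be missing there, with 12% of 5-probe losses of 1 log2 unit found.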

Other observations

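The counts below were chosen after the data were seen. Many of the calls sit at a few places. The 78 calls of the 5 profiles fall into 39 loci when calls within 1 Mb are joined, and 5 of these loci hold 27 of the calls, with calls from at least 4 of the profiles each. As 2 of the profiles are differences of the same arrays, a region can count more than once; these loci hold 15 of the 51 calls of single arrays. They lie on chromosome 4 from 32172087 to 32446943, chromosome 8 from 7085255 to 8702950, chromosome 9 from 37531191 to 39613248, chromosome 13 from 89461924 to 89790884 and chromosome 17 from 8056 to 493589. Loci on chromosome 20 from 33533879 to 44468094 and chromosome 5 from 60449538 to 60706975 were called on all 3 stem cell arrays but in neither difference. On chromosome 4 of MPH1-P20, 6 probes from 32172087 to 32244481 averaged -2.03 ± 0.66 (SE), with 2 of the 6 not well above background. Their mean was -0.94 over probes well above background and -0.85 with normexp. Next to them, 19 probes from 32255283 to 32389251 averaged 0.79 ± 0.26, but only 13 of the 19 lay above 0.

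Single probes far from the median were unevenly spread over the samples. Probes below -2 numbered 421 in MPH1-P11, 539 in MPH2-P5, 112 in MPH1-P20 and 0 in the self-hybridisation. Probes above 2 numbered 136, 197, 234 and 0 in the same order. Of the stem cell arrays, MPH1-P20 thus had the fewest probes below -2 and the most above 2. At a cutoff of 1 its 1229 low probes were again the fewest (1760 in MPH1-P11, 2655 in MPH2-P5). Its 1386 high ones were not the most (1104 and 1797). The share of spots well above background on both channels was 99.88% in MPH1-P20, 99.80% in MPH1-P11 and 99.71% in MPH2-P5. Dim spots may add to the low counts, which was not tested. The chromosomes with the highest medians in MPH1-P20 after chromosome 19 were 16, 10 and 20, at 0.143, 0.124 and 0.105, and MPH2-P5 had 0.098, 0.088 and 0.071 there.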
